A study of Caenorhabditis elegans with 3 samples.

How the data were processed

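Trimethylation of lysine 27 of histone H3 (H3K27me3), a mark of silent chromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans of the N2 strain, the standard laboratory wild type. Per the labels' protocols, worms were moved as young adults to plates with FUdR at 20 ug/ml, which prevents growth of progeny, and kept at 20 °C. They fed on HT115 bacteria that carried either the empty L4440 vector or a clone making double-stranded RNA against utx-1, induced with 1 mM IPTG, and were transferred every 4 days. Groups were taken from the sample titles: young control (adult day 3, empty vector), old control (adult day 10, empty vector) and old utx-1 RNAi (adult day 10). Each group had 1 library. No input library was used here.

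The deposited files hold 1 aligned read per line, as chromosome, start, end and strand, so that the values used are read positions, and the reads were counted from them. Every line has a length of 35 bases and the alignment tag U0. Sequencing was on an Illumina 1G Genome Analyzer, per the labels' protocols. The aligner, its filters and the genome build are not given in the sources used here. Positions are therefore given as in the files, counted from 1, without a build name. The gene table used here is of the WBcel235 assembly. On chromosomes I, II, IV and V it lists 2, 2, 2 and 3 genes that end beyond the last read, and on III and X 0. The last read need not be the chromosome end, so a difference of builds was assumed, not shown. The table therefore served only to look up the chromosome of a named gene. The comparisons planned over annotated genes and 25 gene lists were not made for this reason, and windows of 1 kb and enriched regions took their place. What is annotated at the positions named was not analysed here.

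Reads at the same position and strand were counted once. The young control, old control and RNAi libraries held 14443619, 10285885 and 10154467 reads, and 12755408, 9455845 and 9357511 unique reads on the 6 nuclear chromosomes, or 127, 94.3 and 93.3 per kb. The fragment length, from the shift between strands with the highest cross-correlation smoothed over 11 bases, was 232, 267 and 231 bp, and reads were moved by 116, 134 and 116 bases to the fragment centre. Of 100270 windows, 5872 with fewer than 100 unique reads over the 3 libraries were left out, as were windows with more than 3 reads per unique read in any library (read stacks, 72 windows, some of them among those with few reads), which left 94342. The rule on read stacks was chosen after the data were seen. Each autosome was divided in 3 equal parts by the position of its last read, the outer parts being called arms and the middle part centre.

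Counts were scaled to the unique nuclear reads of each library, which shows how the mark is distributed but not its total amount per genome. Ratios have 95% exact (conditional binomial) intervals, shares exact Clopper-Pearson intervals and single counts exact Poisson intervals. All cover counting error only, and reads made by PCR without molecular identifiers are not independent molecules. With 1 library per group they compare libraries, not ages or treatments, and no p-value was computed. A window or region was counted as higher or lower by size when its whole interval lay beyond 1.5-fold. Counts drawn from a Poisson distribution with equal rates in the 3 libraries gave the values set beside the observed ones. For regions, the selection of regions was repeated on the simulated counts. Each is a single simulated value whose spread was not measured. The rates were the pooled counts of the windows, which hold counting error themselves.

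Enriched windows held more reads than a Poisson background gives at 1e-05, with libraries thinned to 9357511 reads and the background set at the median window. Those at most 1 window apart were merged, and regions of at least 2 kb were kept. The regions named are the 10 highest and 10 lowest in each main comparison, ranked by the bound of the interval nearest to 1, among regions enriched in any library whose denser library exceeded the median window. This is the rule set for genes. It was moved to regions after the ratios of windows had been seen but before those of regions were computed. Other positions named were chosen after their values were seen, and the text says so. The relative spread is the coefficient of variation of window counts beyond Poisson noise, in libraries thinned alike. Both main ratios contain old control, so for their correlation its reads were split at random into 2 parts, one for each ratio, and 0.5 reads were added to each count.

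The interval step was tested on simulated data with 200 changed windows among 94398. For old against young control, 55% of windows changed 2-fold and 96% of those changed 3-fold passed the size rule, and for RNAi against old control 44% and 96%. Alternatives were all deposited reads, other scalings, no count filter, single strands, equal depth, a stricter threshold, other window sizes and another definition of overlap. The relative spread, the density groups, the ratios over enriched regions and per chromosome, the count of windows between the controls, the simulated values beside windows and regions, the larger windows, the measures of edges, flanks and start positions of the block on X, the tests of technical causes and the alternatives marked as added were chosen after the data were seen. Apart from these and the changes named above, tests and alternatives were fixed before the data were examined. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.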

Results

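H3K27me3 was profiled in 3 ChIP-seq libraries of whole worms: young adults on the empty vector (day 3), old adults on the empty vector (day 10) and old adults on RNAi against utx-1 (day 10), the gene of an H3K27 demethylase. The libraries held 14443619, 10285885 and 10154467 reads. Repeated positions took 11.6%, 7.99% and 7.76% of the nuclear reads. No group had a replicate, so no difference below has a replicate check.

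The 3 profiles were similar. Across 1 kb windows the Spearman correlation was 0.922 between old and young control and 0.921 between the RNAi library and old control. Across 100 kb bins it was 0.984 and 0.994. The counts of a bin rise with its number of windows kept, which the libraries share, and this raises the values for bins. Neither windows nor bins are independent replicates. Unique reads were denser on X than on the autosomes, 1.14-fold in young control, 1.197-fold in old control and 1.18-fold after RNAi. The autosome arms had 0.885, 0.858 and 0.872 times the density of the centres in the same order. These densities count all windows, and bases to which no read can be aligned were not measured. Differences in density between parts of the genome therefore need not be differences in the mark. Among chromosomes of young control, III and I were the least dense, at 0.895 and 0.916 times the genome mean.

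**Figure D1:**
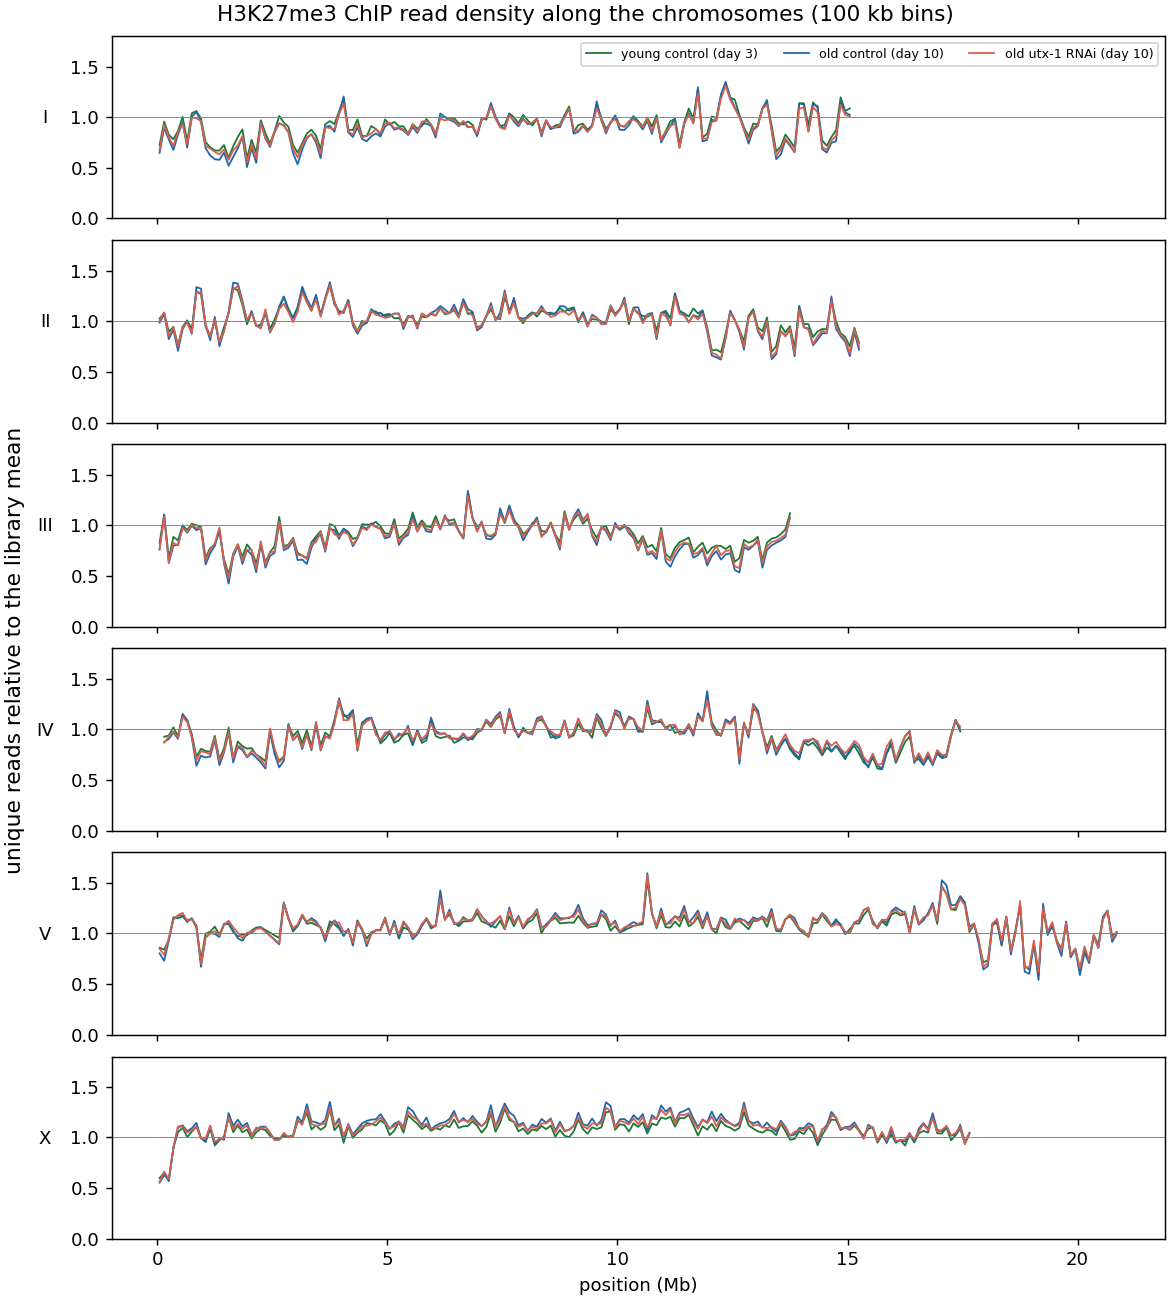
Unique reads in 100 kb bins relative to the library mean (y axis, linear, no unit) along the 6 nuclear chromosomes (x axis, Mb), 1 line per library. The lines run close together, and on X old control lies above young control in 166 of 177 bins.

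The target of the RNAi was looked at first. According to the gene table utx-1 lies on X. One block on X, from 8561428 to 8562480 (1053 bp), held 46856 reads in the RNAi library (95% Poisson interval 46433 to 47282), 247 in old control (217 to 280) and 505 in young control (462 to 551). With all reads, RNAi over old control was 192-fold (170 to 219). With unique reads it was 9.09-fold (7.93 to 10.5), a measure that saturates because 97.01% of start positions in the block held a read. Depth went from under 2 to over 20 times the local median within 3 bases at the left edge and 6 bases at the right edge. In the 2 kb on both sides the ratio of unique reads was 1.06 (0.934 to 1.19). Of 55163 windows of 1 kb with at least 100 reads in either library, 2 exceeded 5-fold between RNAi and old control, both in this block. The block was found from the reads, and its position relative to the annotated utx-1 gene was not analysed here; transcript levels were not measured.

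**Figure D2:**
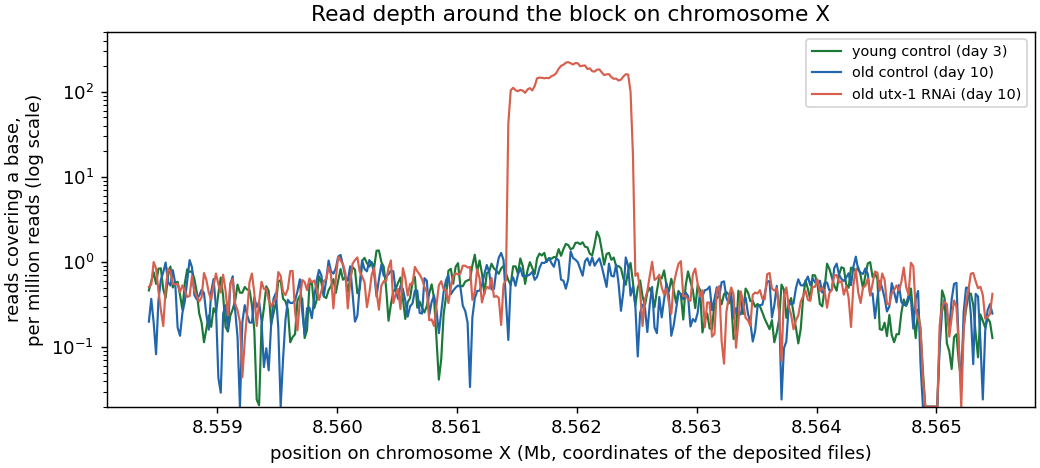
Reads covering a base, in RPM (y axis, log scale, values under 0.02 drawn at 0.02), around the block on X (x axis, Mb in the files' coordinates), in steps of 20 bases, 1 line per library. The RNAi library lies far above both controls between 8561428 and 8562480 and level with them outside.

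Old was compared with young control to ask how the mark is distributed at the later age. X held a larger share of reads in old control, and I and III smaller shares. The share of X was 20.44% (95% interval 20.42 to 20.47) in old and 19.60% (19.58 to 19.62) in young control, a ratio of 1.043 (1.041 to 1.045). The ratio was 0.963 (0.961 to 0.965) for I and 0.959 (0.956 to 0.961) for III. It was 0.993 for II, 1.000 for IV and 1.012 for V. The arms held 63.2% of autosomal reads in old and 63.9% in young control.

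Dense windows were denser and sparse windows sparser in old control. The relative spread of window densities was 39.6% in old and 35.8% in young control, and larger in old control on 6 of 6 chromosomes, by 3.64 ± 1.55 percentage points (mean and SD over chromosomes). Chromosomes of the same library are not independent replicates. From the sparsest to the densest of 10 density groups, the log2 ratio of old to young control went from -0.17 to 0.07. In the sparsest group the ratio was 0.874 in the arms, 0.956 in the centres and 0.999 on X. At matched density X had a higher ratio than the arms and the centres in 10 of 10 groups.

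**Figure D3:**
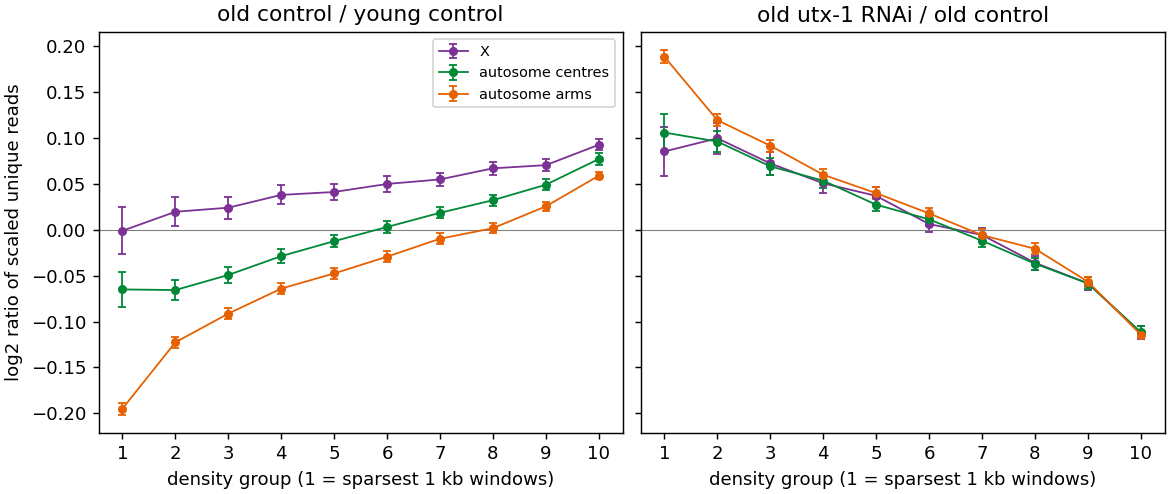
Log2 ratio of scaled unique reads (y axis) in 10 groups of 1 kb windows ordered by density (x axis), for X, autosome centres and autosome arms; bars are 95% counting intervals. Old over young control (left) goes up with density, from -0.17 to 0.07 over all windows, and RNAi over old control (right) goes down, from 0.17 to -0.11.

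At equal depth 13240 windows were enriched in old control and 11604 in young control, against 11880 and 11916 with equal rates. The pooled counts behind these rates hold counting error, which tends to raise the simulated numbers by an amount not measured. They made up 18.6% and 14.4% of the windows on X, 13.4% and 12.61% in the arms and 12.35% and 10.4% in the centres. Enriched windows held 1.77 and 1.74 times the background. They formed 2815 regions covering 10.9 Mb in old control and 2397 regions covering 9.09 Mb in young control, with a median length of 3 kb in both. Of the old control regions 68.2% overlapped a region of young control, and 81.0% of the young control regions overlapped one of old control. Overlap of regions was not simulated. Windows enriched in old control alone of the 3 libraries numbered 2861, against 1715 with equal rates. Those enriched in young control alone numbered 1894, against 1735. Counting error alone thus leaves many windows without a match.

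**Figure D4:**
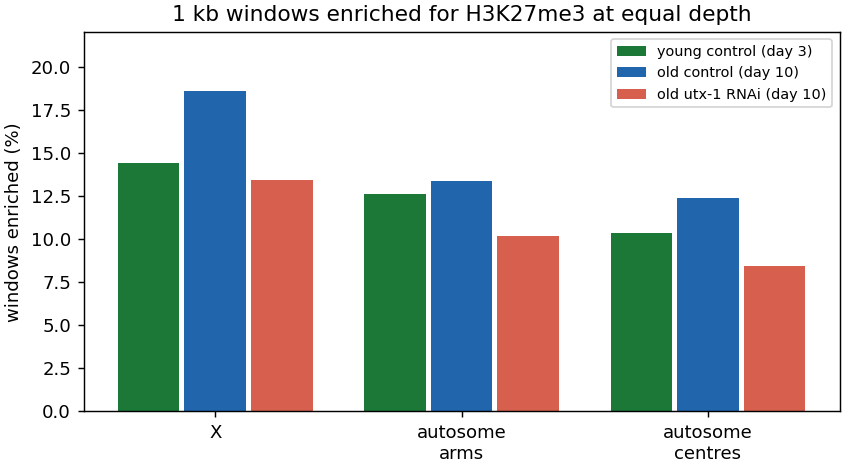
Percentage of 1 kb windows enriched over the median window (y axis, from 0) on X and in the arms and centres of the autosomes. The 3 libraries were thinned to equal depth, and no input library was used. No error bars are drawn, as there is 1 library per group. Old control is highest and the RNAi library lowest in each part, from 18.6% on X in old control to 8.41% in the centres after RNAi.

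Over the 3524 regions enriched in any library, 14.6 Mb in all, the median ratio of old to young control was 1.04, and 73.4% of regions were above 1. Equal rates gave 1.00 and 50.3%. The median was 1.07 for 837 regions on X, 1.05 for 912 in the centres and 1.03 for 1775 in the arms. The interval lay above 1 in 609 regions and below 1 in 96, against 104 and 114 with equal rates. Regions were chosen from the same reads, and windows enriched in old control alone outnumbered those in young control alone (2861 against 1894). Such a choice raises the ratio, and equal rates do not carry it. The densest of the 10 density groups, set on all 3 libraries, had a ratio of 1.05. No region lay wholly beyond 1.5-fold. The longest region, chosen by its length, was on V from 16838001 to 16876000 (38 kb), with 1.63 and 1.71 times the genome mean in young and old control, a ratio of 1.05 (1.02 to 1.09).

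Of the 10 regions ranked highest in old over young control, 6 lay on X and 4 in centres, with ratios from 1.25 to 1.36. The first, on III from 6051001 to 6053000, had 353 unique reads in young and 356 in the shallower old control, a ratio of 1.36 (1.17 to 1.58). On X the region from 9277001 to 9280000 had a ratio of 1.34 (1.16 to 1.53) and the 6 kb region from 7390001 to 7396000 one of 1.25 (1.14 to 1.37). Of the 10 ranked lowest, 6 lay in arms and 4 in centres, with ratios from 0.653 to 0.828. The first, on IV from 15041001 to 15043000, had 401 reads in young and 194 in old control, a ratio of 0.653 (0.547 to 0.777), and the region on IV from 4363001 to 4368000 had 0.751 (0.668 to 0.844). With equal rates the best lower bound was 1.11 and the best upper bound 0.901, against 1.17 and 0.777 observed.

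By the size rule 5 of 94342 windows were higher and 10 lower in old control, against 1 and 0 with equal rates. All 10 lower and 4 of the 5 higher windows lay in arms, with median density percentiles of 3.98 and 10.5; arms held 8023 of the 9435 windows of the sparsest group. The windows singled out here were chosen after their values were seen. On II from 227001 to 228000 there were 60 reads in young and 14 in old control, a ratio of 0.315 (0.162 to 0.570). On X from 17265001 to 17266000 there were 37 and 92, a ratio of 3.35 (2.27 to 5.05). With all deposited reads 9 windows were higher and 16 lower, and with 10 kb windows 2 and 0.

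The RNAi library was compared with old control to ask where the mark differs when the demethylase is targeted. Enriched regions were less dense in the RNAi library, and sparse windows denser. Over the 3524 regions the median ratio of RNAi to old control was 0.937, and 18.5% of regions were above 1, against 1.00 and 50.2% with equal rates. The median was 0.938 on X and in the centres and 0.936 in the arms. The interval lay below 1 in 733 regions and above 1 in 14, against 106 and 100. Windows enriched in old control alone outnumbered those in the RNAi library alone (2861 against 926). Choosing regions from the same reads therefore lowers this ratio, and equal rates do not carry it. The densest of the 10 density groups had a ratio of 0.925. No region lay wholly beyond 1.5-fold.

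After RNAi 9676 windows were enriched at equal depth, against 11935 with equal rates. A window needed at least 142 reads in the RNAi library and 140 in both controls, because the median window held 96 and 95 reads. This lowers the counts of the RNAi library by an amount not measured. They made up 13.4% of the windows on X, 10.2% in the arms and 8.41% in the centres. They formed 1941 regions covering 7.37 Mb, of which 88.1% overlapped a region of old control, while 59.7% of the old control regions overlapped one of the RNAi library. These overlaps were not simulated either. Windows enriched in the RNAi library alone numbered 926, against 1762 with equal rates. The relative spread was 33.96%, below that of old control on 6 of 6 chromosomes, with a difference of -5.81 ± 0.875 percentage points (mean and SD over chromosomes), and -3.26 in 10 kb windows. Here too the chromosomes are not independent replicates. The log2 ratio went from 0.17 in the sparsest to -0.11 in the densest group. X held 20.15% of unique reads (20.13 to 20.18), a ratio to old control of 0.986 (0.984 to 0.988). With all deposited reads it was 1.004 (1.002 to 1.006), and 0.985 once read stacks, the block on X among them, were left out. The ratio was 1.015 (1.012 to 1.017) for III and between 0.993 and 1.009 for the other autosomes.

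Of the 10 regions ranked lowest in RNAi over old control, 6 lay on X, with ratios from 0.706 to 0.817. Old control was above young control in all 10, and the RNAi library was below young control in all 10. The first, on IV from 4906001 to 4909000, had 651 unique reads in old control and 485 after RNAi, a ratio of 0.753 (0.668 to 0.848). Its ratio was 1.25 for old over young control and 0.940 for RNAi over young control. The log2 interval of the latter, -0.259 to 0.0803, included equality. On X the regions from 8341001 to 8343000 and from 13748001 to 13750000 had ratios of 0.706 (0.587 to 0.848) and 0.714 (0.596 to 0.854). Their best upper bound, 0.848, was below the 0.892 found with equal rates. The 10 ranked highest had ratios from 1.16 to 1.29, the first on V from 18719001 to 18721000 at 1.29 (1.11 to 1.49). Its lower bound was under the 1.14 that equal rates gave, a single simulated value, so higher regions were not shown to exceed counting error.

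By the size rule 13 windows were higher after RNAi and 0 lower, against 0 and 0 with equal rates. All 13 lay in arms, where most sparse windows are, with a median density percentile of 2.19. In all 13 the ratio of old to young control was below 1. On V from 20056001 to 20057000, chosen after its values were seen, there were 40 reads in young control, 14 in old control and 47 after RNAi. The ratio of RNAi to old control was 3.39 (1.84 to 6.67). The split was 8 higher and 2 lower when scaled to windows without enrichment, and 11 and 2 when scaled to the median window ratio. With 10 kb windows it was 0 and 0. Of the 1 kb windows 10 lower and 5 higher in old than young control, 10 and 0 had an RNAi to old control ratio above 1. Both ratios contain old control, so a bias or counting error of that 1 library would give these directions too.

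Against young control, the RNAi library had 1.028 times the share of reads on X (1.026 to 1.030) and 0.972 and 0.973 times those on I and III. By the size rule 2 windows were higher and 0 lower, against 0 and 1 with equal rates. The median ratio over the enriched regions was 0.980, and 1.00 on X. In 42.95% of 9971 windows of 10 kb the RNAi value lay between those of the controls, against 31.5% with equal rates. A bias of the old control library alone would raise this share as well. The RNAi library lay below both controls in relative spread (33.96%, young control 35.8%). It also had fewer enriched windows (9676, young control 11604), with the slightly higher minimum of reads given above.

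Both main ratios contain old control, which makes them opposite by construction. Across 10 kb windows their Pearson correlation was -0.628, and equal rates gave -0.532. The covariance was -0.00768 against -0.00255 simulated, a difference of -0.00513. With the reads of old control split between the ratios the correlation was -0.335 (equal rates 0.0155). Across 1 kb windows it was -0.0897, from -0.110 on I to -0.0220 on X, but -0.0136 and -0.0107 with reads of the plus or minus strand alone. Single strands had to meet the same minimum of reads per window with fewer reads, so more sparse windows were left out. In the sparsest density group the log2 ratios were -0.17 for old over young control and 0.17 for RNAi over old control. The single-strand values thus cover a different set of windows, and how far this changes them was not tested. Splitting removes shared counting error but not a bias of that library, and windows are not independent replicates.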

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

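The tests here were chosen after the patterns were seen; for the collapsing of repeated positions alone, the bound was written before its value was computed.

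The block on X was a signal in reads that the comparisons leave out, 192-fold above old control with all deposited reads. A gain of H3K27me3 on chromatin would taper over a fragment and reach the flanks, but the 2 kb flanks were at 1.06-fold (0.934 to 1.19), and copies of a few molecules would leave most start positions empty, but 97.01% held a read. A candidate explanation is DNA of the RNAi clone carried over from the food bacteria, since depth rose from under 2 times the local median to 0.9 of the median depth inside the edge over 28 bases at the left and 35 at the right, about a read and less than a fragment (231 bp). This measure and its bound of a fragment replaced others after the values were seen, and a bound of under a read (35 bases) would not be met at the right edge. The clone's sequence was not compared, and a small gain of the mark beneath the excess stays open.

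Old control had the widest range of densities. Depth does not account for it, as the RNAi library, of like depth, differed by -5.81 percentage points (-3.26 in 10 kb windows), nor does the collapsing of repeated positions, as the difference from young control was 3.204 points with all reads kept. Fragment length cannot be told apart from the sample, because old control was the 1 library at 267 bp; the libraries of 232 and 231 bp differed by 2.17 points. For RNAi against old control, more evenly spread background reads in the RNAi library also cannot be told apart. At matched density X and the arms differed by -0.018 ± 0.031 log2 units (SD over 10 density groups). However, background set to fit the densest group predicts a log2 ratio of 0.33 in the sparsest, where 0.17 was seen. Bases to which no read can be aligned were not measured. Such background in the RNAi library would not change the difference between old and young control. More background in young control was not fitted and stays open for that difference. Age and RNAi stay open as untested.

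X held a higher share of reads in old than young control. An even background would act alike at matched density, but X exceeded the arms in 10 of 10 density groups. The mean was 0.093 ± 0.048 log2 units, where the SD over groups of the same libraries is not an error. The difference went from 0.194 in the sparsest to 0.0337 in the densest group. Bases to which no read can be aligned were not measured, so background is not excluded. Fragment length is not the whole cause, since the RNAi library exceeded young control, of like length, 1.028-fold, nor are repeated positions and read stacks, with 1.044-fold when all reads were kept and stacks left out. GC content was not tested, as no genome sequence was used here. Age stays open as an untested hypothesis, with 1 library per age.

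Mitochondrial reads, which the comparisons do not use, were at 778 RPM (763 to 792) in young control and 855 RPM (837 to 873) in old control, 1.10-fold higher (1.07 to 1.13). They were at 906 RPM (887 to 925) in the RNAi library, 1.06 times old control (1.03 to 1.09).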

How the results depend on the processing

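Windows of 5 and 10 kb, read stacks kept or left out of all reads, the region medians with their scalings and all settings for the relative spread were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and no replicate could be left out. The alternatives planned over promoter regions, gene lists and GC content were not run, as no annotation or sequence of the files' build was used here. Counts by the size rule follow in the order old over young control (higher, lower), RNAi over old control (higher, lower) and RNAi over young control (higher, lower), and were 5, 10, 13, 0, 2 and 0 as reported. They were 9, 16, 16, 5, 5 and 0 with all deposited reads, 5, 7, 8, 2, 2 and 0 scaled to windows without enrichment, 5, 10, 11, 2, 2 and 0 scaled to the median window ratio, 22, 19, 28, 3, 12 and 2 with no filter on low counts, 1, 5, 8, 1, 4 and 2 with plus-strand reads alone, 1, 7, 6, 3, 3 and 1 with minus-strand reads alone, 4, 8, 6, 1, 2 and 0 at equal depth, 6, 0, 1, 0, 1 and 0 in 5 kb windows, 2, 0, 0, 0, 0 and 0 in 10 kb windows, and 5, 10, 15, 0, 4 and 0 with read stacks kept. Single strands hold fewer reads, so the same minimum of reads leaves out more sparse windows, which also bears on the single-strand values below. Larger windows are fewer. Otherwise the cause was not tested. The relative spread was larger in old than young control in the settings run (3.03 to 4.36 points) and smaller after RNAi than in old control, with a difference of -3.90 points in 5 kb and -3.26 in 10 kb windows. The split correlation of both ratios was -0.0136 and -0.0107 on the plus and minus strand alone, -0.290 in 5 kb and -0.373 in 10 kb windows. The last counts all unique reads of each 10 kb window and draws the split anew, while the -0.335 reported sums the 1 kb windows kept. The share of X, RNAi over old control, turned from 0.986 to 1.004 with all deposited reads; leaving out read stacks gave 0.985, which places the cause in them. The share of X, old over young control, was 1.046 with all deposited reads and 1.049 without enriched windows, where the share of the arms was 0.985 and, for RNAi over old control, 1.0101. Region medians kept their direction, at 1.06 and 1.05 for old over young control and 0.913 and 0.927 for RNAi over old control, scaled to windows without enrichment and to the median window ratio. At a threshold of 1e-08, enriched windows covered 6194 kb in young control, 7569 in old control and 5002 after RNAi, the order reported. Regions of old control shared with young control were 61.2% at that threshold, 80.5% in 2 kb windows, 72.0% with all reads and 63.9% when at least 0.5 of a region had to overlap; regions of the RNAi library shared with old control were 90.5%, 90.0% and 85.99% in the last 3. The block on X moved from 9.09 to 192 with all reads. Of all values by setting, 58 moved, 1 reversed and 59 stayed within their spread or, for counts, within 1.5 times. Depth limits single windows: at 94.3 unique reads per kb in old control, 44% of simulated 2-fold changes were recovered for RNAi over old control.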

Other observations

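The windows of 10 kb below were chosen after their values were seen. Some sparse windows were denser in old control than in both other libraries. On I from 13090001 to 13100000 there were 190 unique reads in young control, 303 in old control and 194 after RNAi, a ratio of 2.15 (1.79 to 2.59) for old over young control and 0.647 (0.537 to 0.777) for RNAi over old control. On X from 17260001 to 17270000 there were 422, 571 and 397, with ratios of 1.83 (1.61 to 2.07) and 0.703 (0.617 to 0.800). In the opposite direction, III from 11310001 to 11320000 had ratios of 0.639 (0.548 to 0.744) and 1.43 (1.21 to 1.69), and I from 1750001 to 1760000 had 0.626 (0.524 to 0.746) and 1.47 (1.22 to 1.78). Their density percentiles were 0.392, 3.49, 1.66 and 0.674. Both ratios contain old control, so their opposite directions are not independent.

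Across 9925 windows of 10 kb, log2 ratios from plus-strand and minus-strand reads had a Pearson correlation of 0.605 for old over young control and 0.358 for RNAi over old control. Windows are not independent replicates.

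Near the end of chromosome I, the arm in which the ribosomal RNA gene array of this species lies, 7 windows of read stacks between 15060001 and 15069000 held 15060.5 RPM of all nuclear reads in young control (14997 to 15124), 13621 RPM in old control (13550 to 13693) and 12459 RPM in the RNAi library (12390 to 12528). Reads of near-identical repeats cannot be assigned to a copy.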
